A study of Mus musculus with 9 samples.

How the data were processed

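RNA from 3 lines of mouse embryonic fibroblasts (MEFs), cultured from female embryos at embryonic day 12.5, was measured on 9 expression arrays. The lines carried both working copies of Oga (WT), 1 copy (Het) or 0 copies (KO), and 3 arrays were run per line. Oga encodes O-GlcNAcase, the enzyme that removes the sugar O-linked N-acetylglucosamine from proteins. Per the labels' protocols, total RNA was extracted with Trizol, treated with DNase, and labelled with biotin by the standard Affymetrix procedure. The series' design text states that mice with a floxed Oga allele were crossed with MMTV-Cre mice, that heterozygous offspring were intercrossed, and that the 3 arrays per line are technical replicates. The labels give the 3 arrays of a genotype the same line code, so each genotype is represented by 1 line. Every limma p-value therefore rests on the spread between arrays of a line. The tests of gene lists, of the chromosome and of gene pairs compare genes, not embryos. In all of them genotype cannot be separated from any other difference between the 3 lines.

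The authors deposited a table of 45101 probe sets with values on a log2 scale. The base of the logarithm was taken from the values, which ran from 3.25 to 15.1. GCOS and Partek were used per the submitters' processing notes, without versions. Which of them made the deposited values, and with which background correction, normalization and summarization, is not given in the sources used here. Array medians lay between 6.87 and 6.95, so the deposited values were used without further normalization. No scanner files were used here. On arrays of the same line, between 2.22% and 4.54% of probe sets held exactly equal values, and between lines 1.93% to 3.83%, so equal values were not a mark of an array deposited more than once.

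The 64 control probe sets were left out. Gene symbols came from the platform annotation supplied with the data: 34945 probe sets carried 1 symbol, 932 several and 9160 none, and only those with 1 symbol were named. Entrez identifiers of 34736 probe sets matched the mouse RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. That table served for names and for which genes lie near each other, and no positions are given because the build behind the annotation is not given in the sources used here. Probe sets in the lowest 40% by mean over all 9 arrays, below a log2 value of 6.22, were left out, which left 27022. Of the called genes, 49 between KO and WT, 5 between Het and WT and 28 between KO and Het had a mean below this value in the lower line. For each gene the probe set with the highest mean was kept, giving 12962 genes. Of these, 5995 had several probe sets past the filter.

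Differences between lines were tested with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, in a model with 3 lines and all 9 arrays. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05 and its difference reached 2-fold. The words rose, fell and changed are kept for genes and lists that passed the test. Oga, Ogt and sex-linked probe sets were also fitted among all probe sets. Gene lists, 39 in number, covered pathways, developmental gene groups and markers of other cell types that a fibroblast culture can hold. Each was tested in the 3 comparisons with camera at a preset correlation between genes of 0.01, adjusted over all 117 tests, and again with the correlation estimated from the data. Called genes on the chromosome of Oga, and within 20 Mb of it, were set against all other genes with two-sided Fisher's exact tests. Genes were named by rule: Oga and Ogt, the 10 largest rises and 10 largest falls among the called genes of each comparison, leaving out clone names, and up to 4 called members of each list spoken of, or up to 2 members where none was called. Groups, tests, gene lists, alternatives and this rule were fixed before the data were examined, except the tests, simulations and genes that the text names as added or chosen after a result was seen.

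The steps were tested on simulated data for the comparison of KO with WT, over 12962 genes. Of 50 genes with a simulated difference of 1 on the log2 scale, 48% were called, and of those with 1.5 or 2, 100%. None of the 12762 unchanged genes was called, and 13 passed the adjusted p threshold. The simulated spread was that between arrays, which is small beside 2-fold, so this gives no rate of calls from other differences between lines. Alternatives covered quantile normalization, median centring, other filters, other ways to choose probe sets, other fold minimums, a replicate block, fits of only the compared lines, a trended and robust variance, and each array left out. Expression arrays give no read depth, and the number of arrays and lines limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.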

Results

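The data set comprised 9 expression arrays of mouse embryonic fibroblasts, 3 for each of a WT, a Het and a KO line of the O-GlcNAcase gene Oga. MEFs are primary cultures grown from minced embryos and are mainly fibroblasts. The comparisons ask how gene expression differs when 1 or both copies of Oga are lost. Array values correlated at r = 0.997 to 0.999 within the WT line and at 0.998 to 0.999 within the Het and KO lines. Between lines the range was 0.993 to 0.996 for WT with Het, 0.993 throughout for Het with KO and 0.989 to 0.991 for WT with KO. The 3' minus 5' difference of the actin control probe sets, a sign of RNA quality, was 0.07 ± 0.011 (SD, n = 3) in WT, 0.11 ± 0.015 in Het and 0.07 ± 0.019 in KO arrays on the log2 scale. The same difference of the GAPDH control probe sets was -0.08 ± 0.0097 in WT, -0.0020 ± 0.0059 in Het and -0.07 ± 0.032 in KO arrays.

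Oga was lowest in the KO line and intermediate in the Het line. Its most abundant probe set read 11.92 ± 0.033 (SD, n = 3 arrays) in the WT line, 11.16 in each of the 3 Het arrays and 6.06 ± 0.026 in the KO line. The KO line was below WT by a log2 difference of -5.86 (limma adjusted p = 2.8e-13 among all probe sets), with a KO mean under the low-value cut of 6.22, and the Het line was 1.70-fold below it (log2 difference -0.76). All of the other 5 Oga probe sets were also lower in the KO line, by log2 differences from -4.76 to -1.42. Their KO means ran from 4.91 to 6.47, most of them under the same cut, so these sizes hold for the deposited values only. In the Het line 4 of them passed the adjusted p threshold, from -1.29 to -0.43, and 1 did not (-0.15, adjusted p = 0.392). The probe set at -0.43 did not pass in the fit of the compared lines alone or when 4 of the arrays were each left out in turn, with values from -0.55 to -0.27 over left-out arrays. Which part of the gene was deleted is not given in the sources used here. Ogt, which encodes the transferase that adds the same sugar, was lower in the KO than in the WT line by a log2 difference of -0.40 ± 0.056 (SE, limma adjusted p = 3.2e-04 among all probe sets) at its most abundant probe set, which is short of 2-fold. The other 4 Ogt probe sets lay between -0.18 and 0.02 in that comparison, so the size of the Ogt difference depends on the probe set. Xist, the RNA that coats the inactive X chromosome, read 13.45 in WT, 13.43 in Het and 13.15 in KO arrays at its most abundant probe set. The other 2 Xist probe sets differed from WT by 0.30 (adjusted p = 0.00972) and 0.24 (adjusted p = 0.145) in Het and by -0.20 and -0.44 in KO, while the probe sets of the Y-linked genes Eif2s3y, Kdm5d and Uty stayed between 3.57 and 4.73 in all 3 lines.

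**Figure D1:**
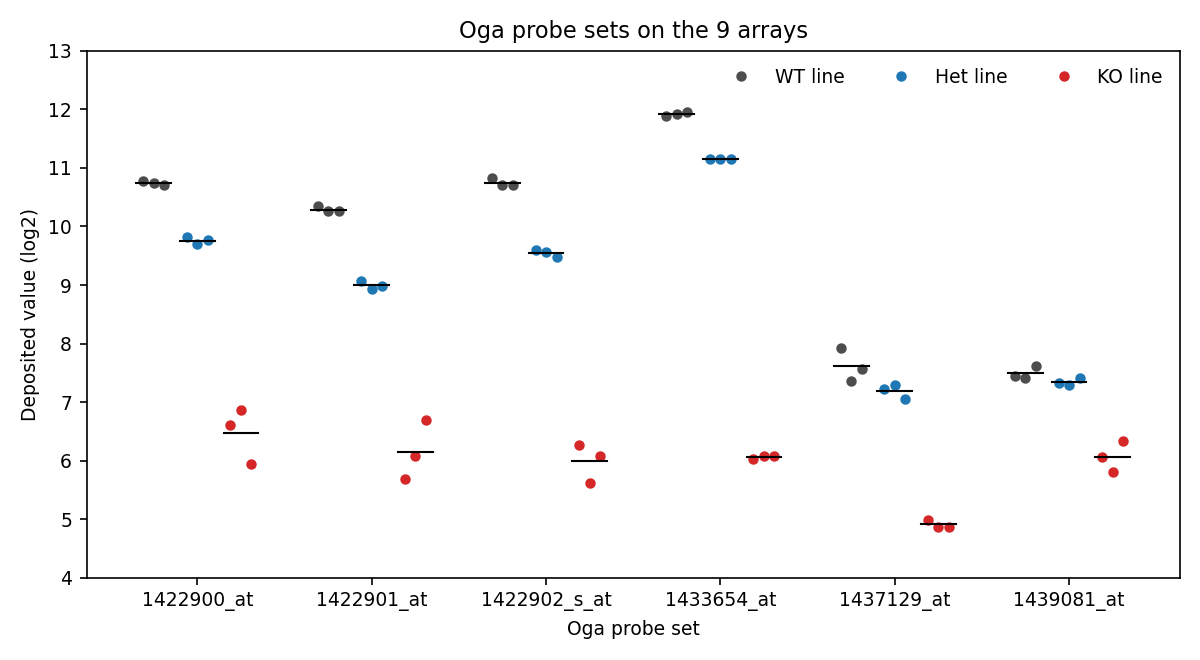
Deposited log2 values of the 6 Oga probe sets (x axis) on each of the 9 arrays; points are arrays and black lines are the means of the 3 arrays of a line. All 3 KO arrays lie below the WT and Het arrays at every probe set, with means of 6.06 in KO against 11.92 in WT at the most abundant probe set.

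Loss of both Oga copies was compared first. In the KO line 462 of 12962 genes were called against WT, of which 334 fell and 128 rose. After Oga, the largest falls in deposited values were in Scara5, a ferritin receptor (log2 difference -4.05 ± 0.055, SE, n = 3 arrays per line), Egfl6, a secreted matrix protein (-3.56 ± 0.15), Ifi202b, an interferon-inducible gene (-3.55 ± 0.071), Lgr5, a receptor for R-spondins (-3.14 ± 0.15), and the water channel gene Aqp4 (-3.03 ± 0.071). F13a1, which encodes the A subunit of coagulation factor XIII, fell by 2.94, the cartilage collagen gene Col9a1 fell by 2.84 (-1.86 with the mean of its probe sets), Lgi2 fell by 2.67 and the hypoxia-inducible Ndufa4l2 fell by 2.64. The KO means of Egfl6 (5.15), Ifi202b (5.18) and Aqp4 (5.39) lie below the low-value cut of 6.22, so the sizes and order of these falls hold for the deposited values only. The largest rise was in Perp, a membrane protein gene induced by p53 (7.67-fold, log2 difference 2.94 ± 0.097). It was followed by the serotonin receptor gene Htr1b (2.18; 1.20 with the mean of its probe sets), the epithelial adaptor gene Sfn (2.17), the pericyte gene Rgs5 (2.13), the chemokine gene Ccl20 (1.97) and Hbegf, a ligand of the EGF receptor (1.95). Klhl30 (1.93), the inducible cyclooxygenase gene Ptgs2 (1.88), and the sarcomere genes Tnni1 (1.83) and Ldb3 (1.82) completed the 10 largest rises. These genes had limma adjusted p-values from 1.9e-15 for Oga to 2.5e-07 for Ldb3. Without a fold minimum 6881 genes passed the adjusted p threshold. Of the 20 genes, 9 had other probe sets past the filter, and 0 of these went the opposite way. Over all calls in this comparison 169 genes had other probe sets past the filter; in 66 of them every other probe set was under 2-fold, and in 3 at least 1 went the opposite way.

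Macrophage genes gave the largest shift of any list in the KO line. Among 19 measured macrophage and blood markers, 18 fell, 0 rose and 1 was not called, with a median log2 difference of -1.69 (camera adjusted p = 1.3e-15). The lysosomal glycoprotein gene Cd68 fell by 2.63, the pore-forming protein gene Mpeg1 fell by 2.02, the lysozyme gene Lyz2 fell by 1.89 and the complement gene C1qc fell by 1.87. Lyz2 was abundant in every line, with means of 13.77 in WT, 13.53 in Het and 11.88 in KO. Interferon-stimulated genes fell as well: 15 of 34 fell, 0 rose and 19 were not called, with a median of -0.94 (camera adjusted p = 1.9e-12). Among them Ifit1, which binds foreign RNA, fell by 2.39, Rtp4 fell by 2.05, the ISG15 protease gene Usp18 fell by 2.01 and Oasl2 fell by 1.93. In the antigen presentation list the median was -0.44 (camera adjusted p = 2.5e-04), and 1 of 11 measured genes, the immunoproteasome subunit gene Psmb8, fell (-1.44). With an estimated correlation none of these lists passed: adjusted p = 0.0973 with an estimated correlation for the macrophage markers, 0.0765 for the interferon list and 0.256 for antigen presentation. Adjusted over the list alone, 19 macrophage markers, 31 interferon-stimulated genes and 10 antigen presentation genes passed the adjusted p threshold, and 18, 15 and 1 of them also reached 2-fold. All were lower except 1 interferon-stimulated gene. Of all 12962 genes 53.1% passed the threshold in this comparison, so such counts are to be read beside that share.

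Genes of contractile cells rose in the KO line, where the macrophage median was -1.69. Among 19 skeletal muscle markers 10 rose, 0 fell and 9 were not called (median 1.06, camera adjusted p = 2.6e-08). These included the slow troponin gene Tnni1 (1.83), the cardiac and skeletal actin genes Actc1 (1.69) and Acta1 (1.61), and the cardiac troponin gene Tnnt2 (1.45). Of 15 smooth muscle and pericyte markers 4 rose and 0 fell (median 0.66, camera adjusted p = 6.1e-07), namely Rgs5 (2.13), the calponin gene Cnn1 (1.65), Mcam (1.35) and the desmin gene Des (1.15). The list of TGF-beta targets and myofibroblast genes shifted upward (27 measured, median 0.47, camera adjusted p = 1.0e-06), with 3 members that rose and 2 that fell. Cnn1 and the activin subunit gene Inhba (1.38) were among those that rose, while the TGF-beta-induced matrix gene Tgfbi fell by 2.01 and the transcription regulator gene Id2 fell by 1.13 (-0.99 with the mean of its probe sets). These lists share members: Des is in both muscle lists, and Acta2, Tagln and Cnn1 are in both the smooth muscle and TGF-beta lists. They are therefore not independent of each other. None of the 3 lists passed with an estimated correlation: adjusted p = 0.0765 with an estimated correlation for skeletal muscle, 0.0973 for smooth muscle and 0.0765 for TGF-beta targets. In the order given, 16, 14 and 23 members passed when adjusted over the list alone, and 10, 4 and 5 of these reached 2-fold. Among those that passed, 15, 12 and 19 were higher and 1, 2 and 4 lower. The share of all genes that passed the adjusted p threshold was 53.1%.

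Targets of p53 formed another list that rose in the KO line, with 6 of 22 measured members called higher, 0 lower and 16 not called (median 0.59, camera adjusted p = 1.2e-10; adjusted p = 0.0765 with an estimated correlation). Perp (log2 difference 2.94), Pmaip1, a pro-apoptotic BH3 protein gene (2.83-fold), Rprm (1.45) and Btg2 (1.34) had the largest rises. When adjusted over the list alone, 20 members passed, 19 of them higher, and 6 of the 20 reached 2-fold. Heat shock protein genes rose in 2 of 13 cases, Hspa1b (1.37) and Cryab (1.10), with a median of 0.15 (camera adjusted p = 2.5e-04; adjusted p = 0.146 with an estimated correlation). Of 18 immediate early genes, Dusp1 (1.44) and Egr2 (1.12) rose (median 0.17, camera adjusted p = 0.0132; adjusted p = 0.463 with an estimated correlation). The keratin genes Krt18 (1.68) and Krt19 (1.26) rose among 10 epithelial and mesothelial markers (median 0.25, camera adjusted p = 0.00187; adjusted p = 0.165 with an estimated correlation). The Hox A list also passed, with a median of 0.19 over 9 genes, 0 of them called (camera adjusted p = 0.0185; adjusted p = 0.378 with an estimated correlation); its members with the largest differences were Hoxa5 (0.50) and Hoxa11 (0.48). The counts adjusted over the list alone were 8 heat shock, 16 immediate early (11 higher, 5 lower), 7 epithelial and 8 Hox A genes (7 higher, 1 lower). Since 53.1% of all genes passed the adjusted p threshold in this comparison, these counts alone do not set the lists apart.

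Hypoxia, adipocyte and glycolysis genes moved the other way in the KO line. Of 18 hypoxia response genes 3 fell and 0 rose (median -0.34, camera adjusted p = 5.2e-04), namely the mitophagy receptor gene Bnip3 (-1.17), Ankrd37 (-1.12) and the carbonic anhydrase gene Car9 (-1.09). Of 15 adipocyte differentiation genes 3 fell (median -0.59, camera adjusted p = 6.6e-04): the preadipocyte gene Dlk1 (-1.75), the fatty acid transporter gene Cd36 (-1.65) and the regulator gene Zfp423 (-1.02). Among 17 glycolysis genes the aldolase gene Aldoc (-1.62) and the lactate transporter gene Slc16a3 (-1.02) fell (median -0.19, camera adjusted p = 0.0119). None of these passed with an estimated correlation: adjusted p = 0.0765 with an estimated correlation for hypoxia, 0.272 for adipocyte genes and 0.378 for glycolysis. Of these lists, 15 hypoxia, 13 adipocyte and 12 glycolysis genes passed when adjusted over the list alone. In each list 1 of them was higher and the rest lower. The share of all genes that passed the adjusted p threshold was 53.1%. Slc16a3 was within 2-fold with quantile normalization (-0.985) or without WT replicate 2 (-0.97), Zfp423 with quantile normalization (-0.97) or without WT replicate 1 (-0.96) or KO replicate 1 (-0.999), and Dlk1 with the mean of its probe sets (-0.96). Cd36 is also made by macrophages, whose markers had a median of -1.69 in this comparison. The collagen and extracellular matrix list did not pass (median -0.06, camera adjusted p = 0.331), although Lum (-2.42), Fmod (-1.83) and Col6a3 (-1.13) fell and Efemp1 (1.34) rose among its 40 members. Neither oxidative phosphorylation (34 genes, median -0.01, camera adjusted p = 0.820) nor the G2/M cell cycle list had a called member.

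**Figure D2:**
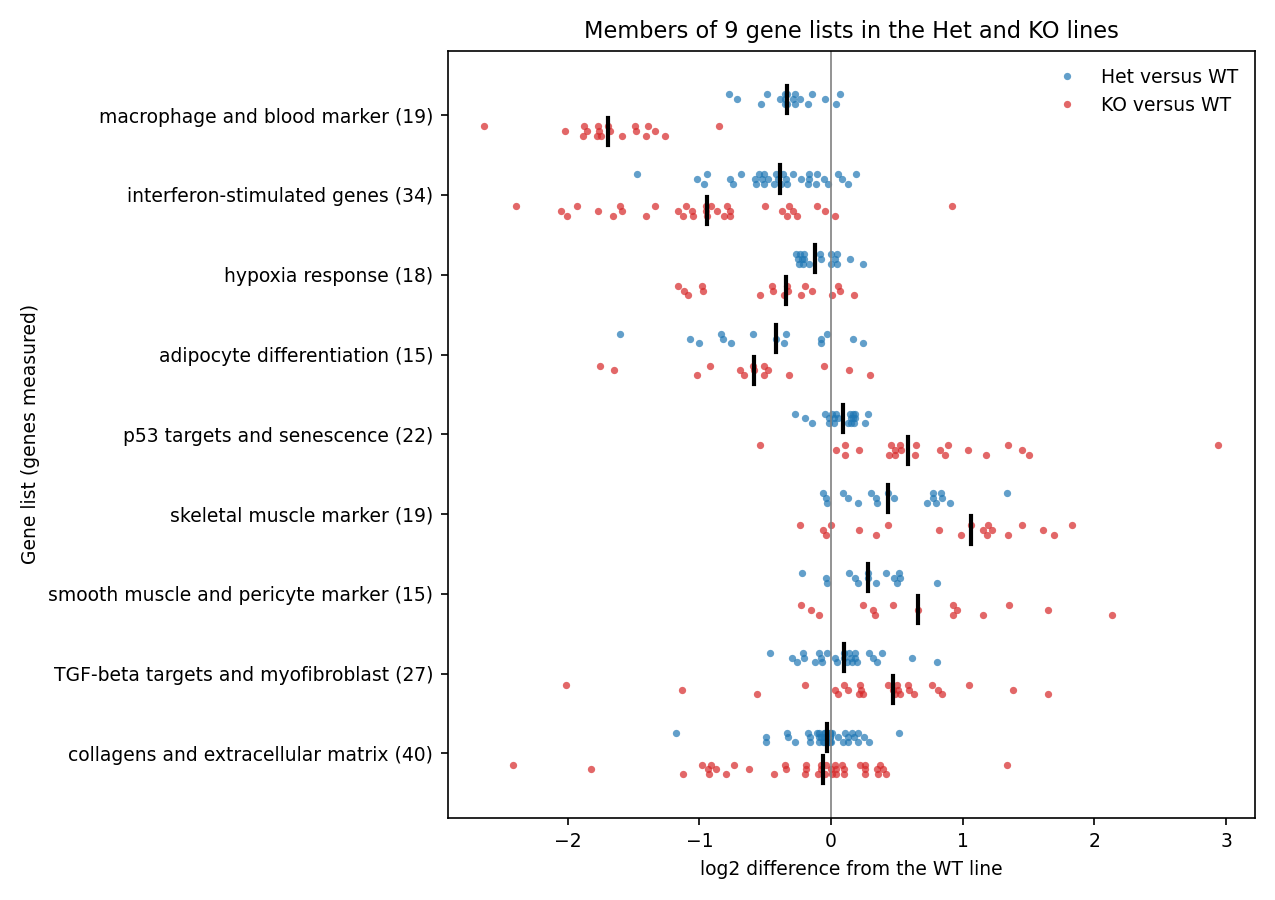
Log2 differences from the WT line (x axis) of the members of 9 gene lists (y axis, with the number of genes measured) in the Het line (blue) and the KO line (red); points are genes and black bars are list medians. Macrophage markers have a median of -1.69 in KO and -0.33 in Het, and skeletal muscle markers of 1.06 in KO and 0.43 in Het.

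The Het line differed from WT in far fewer genes at 2-fold. There 33 genes were called, 26 that fell and 7 that rose, and 4458 passed the adjusted p threshold alone. The largest change was in the agouti gene a, which encodes a signalling protein of pigmentation: it read 5.29 in WT, 11.99 in Het and 5.42 in KO arrays, a rise by a log2 difference of 6.70 ± 0.080 in the Het line (SE, n = 3 arrays per line, limma adjusted p = 2.4e-12). The WT and KO means of a, the WT mean of Gbp2b (5.19) and the Het means of Ang (5.82) and Cxcl5 (6.02) lie below the low-value cut of 6.22, so sizes and order in this paragraph hold for the deposited values only. The interferon-inducible Gbp2b (1.94), the phosphatase gene Ptprv (1.78), the cardiac actin gene Actc1 (1.34), Klhl30 (1.12) and the sialic acid lyase gene Npl (1.09) also rose. Falls in deposited values were largest in the ribonuclease gene Ang (-3.26 ± 0.045), the ciliary gene Rpgrip1 (-2.96 ± 0.049), Tmem87a (-2.50 ± 0.072), the chemokine gene Cxcl5 (-2.34 ± 0.087) and the ubiquitin ligase gene Trim13 (-1.95 ± 0.066). Cxcl15 (-1.66), the lipase inhibitor gene Angptl4 (-1.61), the Wnt antagonist gene Sfrp2 (-1.49), the interferon-stimulated gene Xaf1 (-1.48) and Shisa3 (-1.40) followed. These genes had limma adjusted p-values of at most 1.4e-06. Ang and Angptl4 were measured by probe sets that can detect several transcripts. Another such probe set of Ang was at -3.14, while its remaining probe set, without that mark, was at -0.47.

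Several lists that shifted in the KO line also shifted in the Het line, with smaller medians, where the 3' minus 5' differences of actin (0.11) and GAPDH (-0.0020) also stood above those of WT (0.07 and -0.08). The interferon-stimulated list had a median of -0.39 (camera adjusted p = 2.4e-10), with Xaf1 (-1.48) and Ifit1 (-1.02) called lower among 34 genes. Skeletal muscle markers had a median of 0.43 (camera adjusted p = 1.9e-09), with Actc1 called among 19, and smooth muscle markers one of 0.28 (camera adjusted p = 6.1e-07), with 0 of 15 called. The macrophage and blood median was -0.33 (camera adjusted p = 3.1e-07), also with 0 of 19 called; Cd68 (-0.78) and Cd53 (-0.72) differed most. Of 15 adipocyte genes 3 fell, namely Angptl4 (-1.61), Dlk1 (-1.07) and the fatty acid binding protein gene Fabp4 (2.01-fold lower), with a list median of -0.42 (camera adjusted p = 6.8e-05). With an estimated correlation these lists did not pass: adjusted p = 0.0765 with an estimated correlation for interferon-stimulated genes and for skeletal muscle, 0.0973 for smooth muscle, 0.256 for macrophage markers and 0.227 for adipocyte genes. Between Het and WT 34.4% of all genes passed the adjusted p threshold. Adjusted over the list alone, 28 interferon-stimulated, 14 skeletal muscle, 13 smooth muscle, 16 macrophage and 12 adipocyte genes passed. These 3 calls at the 2-fold limit depended on single arrays: Ifit1 was lost with quantile normalization (-0.99) or without WT replicate 1 (-0.98), WT replicate 3 (-0.997) or Het replicate 1 (-0.97), Fabp4 without WT replicate 2 (-0.98) or Het replicate 1 (-0.91), and Dlk1 with the mean of its probe sets (-0.72) or without Het replicate 1 (-0.95).

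Imprinted genes included some of the falls in the Het line. Of 22 measured members 3 fell, the creatine synthesis gene Gatm (-1.38), Dlk1 (-1.07) and the cell cycle inhibitor gene Cdkn1c (-1.01), and the list median was -0.13 (camera adjusted p = 0.0184; adjusted p = 0.240 with an estimated correlation). The same genes were lower in the KO line, Gatm by a log2 difference of -2.05, Dlk1 of -1.75 and Cdkn1c of -1.69, together with Mest (-1.25), but the list did not pass there (median -0.06, camera adjusted p = 0.203). Cdkn1c was within 2-fold with quantile normalization (-0.99) or without WT replicate 1 (-0.97), Het replicate 1 (-0.98) or Het replicate 2 (-0.98). When all probe sets were tested separately the direction of the list turned (median 0.032), and with the mean of probe sets it did not pass (-0.18). The O-GlcNAc cycling and hexosamine list had a median of -0.13 over 13 genes, 0 of them called (camera adjusted p = 0.0117, adjusted p = 0.356 with an estimated correlation). The list holds the deleted gene Oga itself (-0.76) and was not tested without it. After Oga, the glucosamine-phosphate deaminase gene Gnpda1 differed most (-0.51), and with the mean of probe sets the list did not pass (median -0.07). Autophagy and lysosome genes (median -0.13, camera adjusted p = 0.00191; adjusted p = 0.374 with an estimated correlation) had 0 of 24 members called, with Neu1 at -0.38 and Lamp2 at -0.38; the macrophage median was -0.33 in this comparison, and the lysosome list did not pass in KO against WT (median -0.04, camera adjusted p = 0.470). Neural and glial markers had a median of 0.26 (camera adjusted p = 9.1e-05; adjusted p = 0.235 with an estimated correlation) and 0 of 16 called. In these lists 13 imprinted, 8 O-GlcNAc, 16 lysosome and 12 neural genes passed when adjusted over the list alone, of which 3, 1, 1 and 10 were higher. The share of all genes that passed the adjusted p threshold was 34.4%. A further 8 lists passed with medians between -0.18 (antigen presentation) and 0.19 (Hox C) and with Sfrp2 of the Wnt list as their 1 called member, and their adjusted p with an estimated correlation ran from 0.227 to 0.378. Of these, the Wnt list did not pass with median centring (median -0.19) or without WT replicate 1 (-0.13), the p53 list, with a median of 0.09, did not pass with all probe sets (0.05) or without WT replicate 3 (0.12), and the Hox B list did not pass with no filter on low values (0.10).

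The KO and Het lines were compared to ask what the loss of the remaining copy adds. Of 259 called genes 178 fell and 81 rose in KO relative to Het. Perp (2.92 ± 0.097, SE, n = 3 arrays per line), Serpinb6b (2.01), Rgs5 (1.85), the cardiac ankyrin repeat gene Ankrd1 (1.79), Ccl20 (1.77), Parm1 (1.76) and Htr1b (1.71; 0.92 with the mean of its probe sets) were among the largest rises. In 39 of 99 called genes with other probe sets past the filter, every other probe set was under 2-fold. Ang (2.89), Rpgrip1 (2.87) and Trim13 (2.06), which fell in the Het line, were also among the largest rises. The falls were led by a (-6.57 ± 0.080), Oga (-5.09 ± 0.036), Ifi202b (-3.26 ± 0.071), Scara5 (7.98-fold lower), Lgr5 (-2.91 ± 0.15) and Egfl6 (-2.86 ± 0.15), followed by Npl (-2.55), F13a1 (-2.45), Aqp4 (-2.43) and Ndufa4l2 (-2.20). The KO means of a, Oga, Ifi202b, Egfl6 and Aqp4 and the Het mean of Ang lie below the low-value cut, so the order of these genes holds for the deposited values only. Limma adjusted p-values of these genes were at most 7.7e-08.

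By lists, macrophage and blood markers again moved most between the KO and Het lines, with 17 of 19 lower (median -1.38, camera adjusted p = 4.3e-16) and Cd68 (-1.86), Lyz2 (-1.65), C1qa (-1.60) and C1qb (-1.58) in the lead. The 3' minus 5' differences also stood apart between these lines, at 0.07 in KO against 0.11 in Het for actin and -0.07 against -0.0020 for GAPDH. Of 34 interferon-stimulated genes 8 fell (median -0.42, camera adjusted p = 2.3e-08), including Oasl2 (-1.65) and Ifi27 (-1.60). Targets of p53 rose in 6 of 22 cases (median 0.53, camera adjusted p = 2.9e-10), with Perp, Pmaip1 (1.36), Rprm (1.29) and the ectodysplasin receptor gene Eda2r (1.19) ahead. Among 20 NF-kB targets and chemokines Ptgs2 (1.44) and the cytokine gene Lif (1.22) rose (median 0.20, camera adjusted p = 0.00685). Heat shock genes had a median of 0.28 with 0 of 13 called (camera adjusted p = 2.2e-05), and Cryab (0.90) and Hspa1b (0.88) differed most. None passed with an estimated correlation: adjusted p = 0.0973 with an estimated correlation for macrophage markers, 0.0765 for interferon-stimulated genes, 0.0765 for p53 targets, 0.113 for NF-kB targets and 0.0973 for heat shock genes. With values adjusted over the list alone, 19 macrophage, 27 interferon-stimulated, 20 p53, 14 NF-kB (11 higher, 3 lower) and 11 heat shock genes passed. The share of all genes that passed the adjusted p threshold between these lines was 52.3%. A further 10 lists passed with medians between -0.31 (antigen presentation) and 0.37 (Hox A), and their adjusted p with an estimated correlation ran from 0.0765 to 0.374; of these, the epithelial and mesothelial list did not pass with the lowest 60% left out (0.11).

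Genes called in both comparisons with WT were then counted. The KO and Het lines shared 22 called genes that moved the same way, 4 higher and 18 lower, where independent lists of these sizes would share 0.069 and 0.670. Unchanged groups simulated against the same WT arrays shared 0 in each of 20 simulations, but 0 unchanged genes reached 2-fold in the self-test, so this gives no expectation for the 22. Npl was called in opposite directions, higher in Het (1.09) and lower in KO (-1.46), and 10 genes called in Het were not called in KO. Across 12962 genes, which are not independent replicates, the differences from WT correlated at r = 0.536, against 0.5003 in 100 simulations of unchanged groups, and their covariance was 0.0460 against 0.00167. The 2 differences had the same sign in 66.1% of genes, against 66.7% in the simulations. With 3 WT arrays the controls could not be split into parts of at least 2. Such a split of technical replicates would also not remove a trait of the WT line. The simulations hold only the spread between arrays, while any trait of the WT line enters both differences. The excess of shared genes and of covariance may therefore come in part or in full from the shared WT line.

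Most genes called in the KO line had intermediate values in the Het line. Of the 462 genes, 426 (92.2%) had a Het mean between the WT and KO means, 33 had a Het mean on the other side of WT and 3 a Het mean beyond KO. In 20 simulations, added after this share was seen, with a Het line equal to WT and only the spread between arrays, a mean of 52.3% of the genes called in KO had the Het mean between. The simulations leave out differences between lines that are unrelated to Oga, so these shares do not show an order by the number of Oga copies. The median Het difference was 26.1% of the KO difference, with an interquartile range of 15.2% to 40.2%. For Oga itself at its most abundant probe set the Het difference of -0.76 stood against -5.86 in KO. Perp, with a KO difference of 2.94, had a Het difference of 0.02. Tmem87a fell by 2.50 in Het and by 2.59 in KO.

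**Figure D3:**
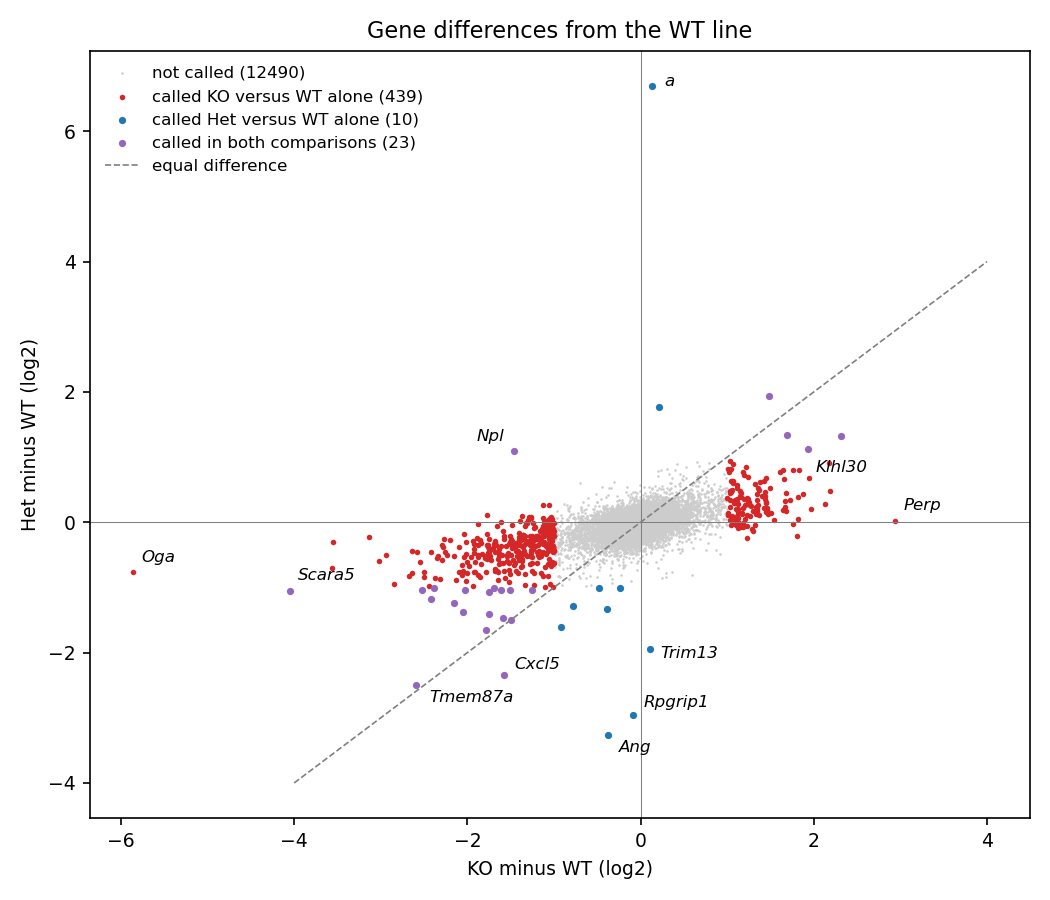
Log2 differences from the WT line for each of the 12962 genes, KO minus WT on the x axis and Het minus WT on the y axis; colours mark the genes called in each comparison and the dashed line marks equal differences. Most genes called in KO lie nearer to 0 in Het, while the agouti gene a (6.70 in Het, 0.13 in KO), Ang, Rpgrip1 and Trim13 stand apart in Het.

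Genes on the chromosome of Oga, chromosome 19, were tested because mice bred around a targeted allele can carry linked sequence of another strain. Between KO and WT, 21 of 458 genes on the chromosome were called (4.59%), against 441 of 12443 elsewhere (3.54%; odds ratio 1.31, 95% interval 0.793 to 2.05, two-sided Fisher's exact p = 0.247, adjusted over 6 tests 0.497). Within 20 Mb of Oga 10 of 207 were called (4.83%, adjusted p = 0.497). Between KO and Het the share on the chromosome was 3.28% against 1.96% elsewhere (Fisher's exact p = 0.0596, adjusted p = 0.358). In the Het line 1 gene of the chromosome was called. An enrichment was therefore not detected with this selection of genes. It passed an unadjusted p of 0.05 under some alternatives, all of which kept Oga itself among the genes.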

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

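The tests in this part were chosen before the result was seen. Probe sets that carry no gene symbol, or several, took no part in the comparisons of genes, and 3852 of them passed the filter on low values. Against WT, the level in the control line, 46 of these were called higher and 29 lower in the KO line, and 18 higher and 4 lower in the Het line. The largest rise in the KO line was a log2 difference of 3.04 ± 0.089 (SE, limma adjusted p = 1.8e-09) at a probe set without a symbol, which was also 1.93 higher in the Het line. The largest fall, -4.35 ± 0.089, was at a probe set with several symbols, among them Ifi202b, which is already named among the largest falls in the KO line. The WT mean of the former (6.07) and the KO mean of the latter (4.17) lie below the low-value cut of 6.22, so sizes and order hold for the deposited values only.

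The 6 arrays of each pair of lines can be split into groups of 3 in 10 ways, so the share of splits with as many called genes cannot go below 0.1. Between KO and WT the real split called 462 genes and the other splits at most 0, so 1 of 10 splits, the real split itself, reached that number. Between Het and WT it called 33 and the others at most 0, again 1 of 10, and between KO and Het 259 and at most 0, also 1 of 10. The arrays of a line are technical replicates, so every other split mixes both lines within its groups. These counts therefore cannot tell whether the calls come from chance differences between embryos.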

How the results depend on the processing

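All alternatives were fixed before the result was seen except the test of chromosome 19 without Oga itself and the pairs of Het genes without Ang, Rpgrip1 and Trim13 (1 pair), and the cause of each change was not tested except where named. Leaving out each array in turn gave 456 to 464 called genes for KO against WT, 30 to 37 for Het against WT, 252 to 273 for KO against Het, 20 to 24 shared genes, 422 to 431 genes with Het between, and 46 to 48 called lists. With all probe sets tested separately, a larger number of tests, the calls were 777, 97 and 442, with 51 shared and 714 with Het between. With no fold minimum they were 6881, 4458 and 6782, with 2607 shared and 4303 with Het between, and with a 1.5-fold minimum 1241, 236 and 895, with 172 and 1074. The share of called genes that were lower went from 72.3% to 59.4% (KO against WT), 78.8% to 61.1% (Het against WT) and 68.7% to 54.6% (KO against Het) with no fold minimum, and to 63.9% for Het against WT with all probe sets; the share with Het between went from 92.2% to 62.5% with no fold minimum. Of 46 called lists 0 passed with an estimated correlation, where the unadjusted p was below 0.05 for 9, 6 and 9 lists. Over 874 list results under alternatives 819 kept direction and call, and 1 turned, the imprinted list in Het (median 0.032 with all probe sets). Of 3068 results for called named genes under alternatives, 41 lost the call and 0 reversed.

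On chromosome 19 the share of called genes passed an unadjusted p of 0.05 between KO and Het with quantile normalization (3.28%), the lowest 60% left out (4.16%), all probe sets (3.18%; 4.03% within 20 Mb) and without Het replicate 1 (range over left-out arrays 3.28% to 3.49%). Between KO and WT it did with the lowest 60% left out (5.54%), with all probe sets (4.36%, and 5.29% within 20 Mb) and with the mean of probe sets (5.80% within 20 Mb). Between Het and WT it did with all probe sets (1.01% within 20 Mb). Oga itself was kept in all of these settings. With all probe sets, each Oga probe set counted separately, and all were at least 2-fold lower in KO than in WT (-5.86 to -1.42). In Het against WT, those at -1.29 and -1.20 were also past 2-fold. Without Oga itself, and with the genes selected as in the main comparison, the shares were 4.38% (KO against WT) and 3.06% (KO against Het). Neither passed, but neither had passed there with Oga. The alternatives that passed were not run without Oga, so its part in them was not tested. The Oga probe set with a WT mean of 7.62 no longer passed the adjusted p threshold for Het in the fit of the compared lines alone (-0.43). The same held without WT replicate 1 or 3 or Het replicate 1 or 3 (range -0.55 to -0.27).

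Among sex-linked probe sets, an Xist probe set passed the adjusted p threshold for KO against WT with quantile normalization (-0.25), the replicate block (-0.20), a trended variance (-0.20) and 2 left-out arrays, WT replicate 2 and KO replicate 1 (range -0.26 to -0.16). Another Xist probe set no longer passed it without KO replicate 2 (range -0.52 to -0.36), and passed it for Het with the block (0.24). A Kdm5d probe set passed in the fit of the compared lines alone (0.21) and without Het replicate 1 (range 0.18 to 0.26), and a Uty probe set without WT replicate 1 (range -0.0042 to 0.18); both lie near background. With the replicate number as a block, 462, 33 and 259 genes were called, the same genes as without it. Deviations of same-numbered arrays correlated at -0.18 to 0.21, above 0.1 in 2 of 9 pairs, and 4 of 9 arrays correlated best with their own number, so the numbers were not taken to pair arrays. Pseudocount alternatives were not run because the values were already on a log scale. Signal over background limits the Y-linked and other low probe sets, whose differences can be compressed, which was not estimated here.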

Other observations

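The tests of macrophage, interferon, p53 and Het-line patterns in this part were chosen only after the result was seen, except the test of the segment between Ang and Trim13, whose bounds were taken from the observed falls and whose median alone had not been seen. Some genes of limb patterning and body position differed between the KO and Het lines. In KO relative to Het, Lhx9 rose by 1.40 ± 0.054 (SE, n = 3 arrays per line), Hoxd13, a gene of the distal limb, by 1.12 ± 0.045, Hoxa13 by 1.10 ± 0.083 (its Het mean of 5.93 lies below the low-value cut) and the hindlimb gene Tbx4 by 1.07 ± 0.070. In Het relative to WT, Hand2 (-0.98), Hoxa13 (-0.85), Lhx9 (-0.81) and Hoxd13 (-0.76) were lower, all short of 2-fold. As a list, limb and craniofacial genes passed in none of the 3 comparisons (camera adjusted p = 0.968 for KO against WT, 0.253 for Het against WT and 0.889 for KO against Het), while the Hox A list passed in KO against Het (median 0.37, camera adjusted p = 0.00488; adjusted p = 0.333 with an estimated correlation). Tbx4 was within 2-fold with the mean of its probe sets (0.92) and without Het replicate 1 (0.98).

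Other secreted and signalling genes fell in the KO line without their lists passing. The growth factor binding protein gene Igfbp3 fell by 1.66 and Igf1 fell by 1.14, the only 2 called of 23 genes of insulin and IGF signalling (camera adjusted p = 0.443). The Wnt antagonist genes Sfrp2 (-1.49) and Dkk2 (-1.45) fell together with Lgr5 (-3.14). Of 14 cartilage and bone markers 4 fell, led by Col9a1 (-2.84) and Comp (-1.51; list camera adjusted p = 0.104), and the other 2, Matn4 and Sox9, were within 2-fold with quantile normalization (-0.97 and -0.96) or median centring (-0.997 and -0.99) and without some single arrays (Matn4 -0.97 without KO replicate 1, Sox9 -0.92 without KO replicate 3). Among neural and glial markers Gfap fell by 1.88 while Nes (1.24) and Ngfr (1.06; 0.85 with the mean of its probe sets) rose. Of the 39 lists, 14 passed in no comparison.

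Macrophage markers were lower in the KO line, where 18 of 19 measured markers were called and 0 rose, and 0 of the 19 belong to another list. A candidate explanation is that the KO culture held fewer macrophages, since the most abundant markers fell with the rest: Lyz1 from 13.83 to 12.25, Lyz2 from 13.77 to 11.88 and C1qa from 12.57 to 10.79. RNA degradation is argued against by the actin 3' minus 5' difference, which was 5.3e-04 higher in KO than in WT arrays, within 2 SD (0.0309). Whether fewer macrophages also carry the interferon-stimulated genes cannot be told apart in the Het line, where that list's median minus the macrophage median was -0.058 (95% bootstrap interval -0.23 to 0.09). An effect of Oga on macrophages or on the interferon response, or a difference between embryos, stays open and untested.

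Targets of p53 were higher in the KO line. A larger share of fibroblasts, as a loss of macrophages would leave, should raise fibroblast genes alike, but the median of the collagen list lay below that of the p53 list by a log2 difference of -0.65 (95% bootstrap interval over genes -1.04 to -0.46). The collagen list is not a neutral measure of that share, since 3 of its 40 members fell and 1 rose. Other shifts in cell mixture were not tested, although skeletal muscle markers had a median of 1.06. The mean of the array medians was 6.89 in KO and 6.90 in WT, so a shift of whole arrays was small beside the p53 median of 0.59. Quantile normalization therefore had little to change and is no separate test of scaling. Under it the p53 list passed with a median of 0.54 (camera with the preset correlation). Without quantile normalization the p53 list also passed with the preset correlation (camera adjusted p = 1.2e-10), but not with an estimated correlation (camera adjusted p = 0.0765). Whether the difference comes with the loss of Oga or with the history of the line was not tested, since each genotype has 1 line.

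In number 11 genes were called in Het against WT and not called the same way in KO, although 7 of them moved the same way in KO past the adjusted p threshold, short of 2-fold: a, Ang, Angptl4, Dvl2, Fabp4, Hpgd, Npl, Ptprv, Rpgrip1, Sparcl1 and Trim13, of which Dvl2, Hpgd and Sparcl1 were named after their values were seen. Whether a strain difference in linked chromosome segments explains part of them cannot be told apart: 4 of the 55 possible pairs lie within 20 Mb of each other, against a mean of 0.979 in 10000 random draws of tested genes (permutation p = 0.0226), but 3 of the 4 are those of Ang, Rpgrip1 and Trim13 on chromosome 14, seen before the test, and without these genes, a condition added after the first count had passed, it was 1 pair against a mean of 0.497 (permutation p = 0.398). Loss of 1 copy of the segment is argued against, since the 102 tested genes between Ang and Trim13 had a median Het difference of 0.0098 (95% bootstrap interval -0.02 to 0.04). A sequence difference under a probe set cannot be told apart, because other probe sets past the filter exist for only 2 genes, Ang and Dvl2. The other probe set of Dvl2 also fell at least 2-fold (-1.61). For Ang, the probe sets at -3.26 and -3.14 both can detect several transcripts, and the remaining one was at -0.47. Which transcript lies behind the Ang fall is therefore not settled. The labels name a mixed strain background, agouti alleles are known to differ between inbred strains, and an effect of the lost Oga copy was not tested apart from the line.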
